A study of Drosophila melanogaster with 3 samples.

How the data were processed

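Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on 3 biological replicates of whole embryos aged 0 to 18 h from a line expressing CG11504 with a C-terminal GFP tag, per the labels. Per the labels, chromatin was fragmented by sonication to 200 to 800 bp and precipitated with an antibody against GFP, and a control library is named only as a possible control. The replicate numbers come from the labels, which call the replicates biological. The control's own data were not analysed here, nor was any library from flies without the tag or with another tagged protein.

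The authors deposited peak lists in dm6 coordinates: 1 per replicate, 1 from the replicates pooled, and 1 thresholded on the irreproducible discovery rate (IDR). Per the text files deposited beside them, the replicate and pooled lists were called against the same control alignment, and the IDR list was derived from the replicate and pooled lists. The lists therefore share a control and are not independent of each other. The aligner, the peak caller, their versions and the read filters are not given in the sources used here. The read depth of the samples is unknown, so no interval based on reads could be given. Each replicate list and the pooled list end at 30000 peaks, so they were compared by their strongest peaks.

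Every peak has the signal value the authors' caller gave it, relative to the control on a scale that is not stated, so signal was compared only within a list, by rank and by the order of medians. The deposited −log10 q-value reached a ceiling of 4.30 in 10023 of the 10650 IDR peaks and was not used to rank. The summit of a peak, in other words its offset from the peak start, is also the authors' deposited value, and summits were turned into positions counted from 1. Peak regions can carry several summits: the 10650 IDR peaks covered 10064 distinct regions. The column of p-values was not used.

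Genes, transcripts and annotated transposable elements came from Ensembl release 115 (BDGP6.54, in the same coordinates as dm6), and sequence from the NCBI reference genome of the same assembly. Only the 6 arms 2L, 2R, 3L, 3R, 4 and X were used, and transposable elements were left out of the gene set. Computations were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

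A peak counted as shared when summits lay within 100 bp. Replicates were compared over their 10650 strongest peaks, as many as the IDR list holds. Chance levels came from 1000 random placements of the peaks on sequenced bases of the same arm (200, or 50 for overlaps, in the alternatives). Each summit was given the first fitting class of promoter (within 500 bp of any annotated start site), 5' UTR, coding exon, 3' UTR, non-coding exon, intron and intergenic. A gene was called bound when an IDR summit lay within 500 bp of one of its start sites, so that 1 peak can be assigned to several genes. Shares of genes were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 23 gene groups, the 4 classes of tRNA, snoRNA, snRNA and histone genes or the 6 arms and a threshold of 0.05. Fisher's exact test counts genes as independent, although neighbouring genes can share a peak. Medians of signal and means of GC content were compared by permutation tests with 100000 resamples. Intervals of shares are 95% exact binomial intervals over genes or peaks and cover counting error only, and the limit printed for a count of 0 is 3 counts of the total.

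The gene groups were cytoplasmic and mitochondrial ribosomal proteins, proteasome, oxidative phosphorylation, Hox, segmentation, dorsal-ventral and mesoderm, neural, muscle structure, germ line, gut with trachea, blood and fat body, Polycomb and Trithorax, insulator proteins, cell cycle and replication, spliceosome and Pol II, signalling by Notch, Wnt, Hedgehog and EGFR, heat shock and stress, MADF-domain genes, cuticle proteins, odorant with gustatory and ionotropic receptors, chorion and vitelline membrane, antimicrobial peptides, and trypsin-like proteases with accessory gland proteins. Of 929 symbols, 1 (a MADF-domain gene) was not matched in the annotation. Named genes followed a rule: CG11504, the gene nearest to each of the 20 strongest IDR peaks, up to 4 members with the strongest peak and up to 3 without one for each group past the threshold, the member with the strongest peak for the other groups, and the 5 strongest peaks over 2 kb from a start site.

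Sequence within 50 bp of the summits was compared with as many matched positions. For a promoter summit this was the same offset from a start site without an IDR summit within 2 kb, and for other summits a random position on the same arm, over 500 bp from a start site and over 2 kb from IDR summits. All words of 6 bases were tested, with an adjusted p of 0.01 and an odds ratio of 1.5 or 0.67 as thresholds, and 18 preset motifs.

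The tests, gene groups, motifs, named-gene rule and most alternatives were fixed before the data were examined. Alternatives were other promoter windows (250 and 1000 bp), another overlap rule, stricter and looser parts of the lists, start sites of protein-coding genes only, a circular shift of the peaks, other windows and backgrounds for sequence, words of 8 bases, gene lists matched on neighbouring start sites within 5 kb, and leaving out each replicate in turn. Chosen after the data were examined were the tests on the 1000, 500 or 100 strongest IDR peaks and by rank, the palindrome and its controls, matching on annotation class or on a gene's own start sites, a second draw of matched positions, the comparison of ribosomal protein peaks with other promoters, and leaving out replicates for classes, arms, motifs and GC content. The background for the strongest peaks and the choice of control palindromes were changed once after first values had been seen. For IDR summits, bound genes, motifs and GC content, leaving out a replicate kept the IDR peaks matched in both other replicates. The replicate left out had still shaped the IDR list, so this is a stricter part of the same list.

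The steps were tested on simulated data. With no word planted, 0 of 2080 words were called, and of 20 planted words 14, 20 and 20 were called when planted in 2%, 5% and 10% of summits. The run without planted words compared matched positions with a further draw of them. It therefore does not cover calls that follow from the GC content of summits. With no gene group raised, 2% of 200 simulations called any group. These simulations drew each gene as bound independently of its neighbours, whereas in the data neighbouring genes can share a peak. The 2% therefore does not cover false calls that follow from shared peaks. Groups of 70 or more members at 2 times the usual share were recovered in at least 86% of simulations, and those under 30 members in 2% to 31%. The promoter test called 3% of 200 simulations with nothing moved and 100% when 2% of the 10650 summits were moved to start sites.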

Results

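The data are maps of where the Drosophila protein CG11504 was found on DNA in whole embryos aged 0 to 18 h, males and females together. A transgenic line made CG11504 with green fluorescent protein (GFP) at its C-terminal end, chromatin was sheared by sonication to fragments of 200 to 800 bp, and an antibody against GFP pulled down the DNA attached to the tagged protein (ChIP-seq). The samples form 1 group of 3 biological replicates, with no second genotype, tissue or age, so the comparisons are between replicates, between peaks and random positions of the genome, and between groups of genes. Each replicate gave a list of 30000 peaks, as did the 3 replicates pooled. A further list of 10650 peaks, here called the IDR list, holds the peaks that passed the authors' threshold on the irreproducible discovery rate, a measure of how far peak ranks repeat between replicates. Its peaks had a median width of 390 bp and were the 10650 strongest peaks of the pooled list. The sequencing depth is unknown. No library without the tag or with another tagged protein was analysed here, so peaks that many GFP experiments share are counted with those of CG11504 in every result below.

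The 3 replicates found largely the same sites. Of the IDR peaks, 86.9% ± 1.41 (SD, n = 3) had their summit within 100 bp of a summit among the 10650 strongest peaks of a replicate, against 1.63% for random placements on the same chromosome arms. The shares were 86.9%, 88.4% and 85.5% in replicates 1, 2 and 3, and 7692 IDR peaks (72.2%) were matched in all 3. Between pairs of replicates, 80.6% ± 1.44 (SD, n = 3 pairs) of the 10650 strongest peaks were shared. The one-sided permutation p was 0.001 for both shares, the smallest that 1000 placements can give. Signal ranks also ran in parallel: Spearman's rho across peaks was 0.898 for replicates 1 and 2, 0.888 for replicates 1 and 3 and 0.882 for replicates 2 and 3, where peaks are not independent replicates. The IDR list was made from these same replicates, so its share of matched peaks describes the list and is no separate test of it.

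The strongest peak of the IDR list, first in each of the 3 replicates too, lay in a coding exon of InR, the insulin receptor gene (chromosome 3R, 21579403 to 21581875, dm6), 9898 bp downstream of the nearest start site. The next was at the promoter of toc (2L, 3107584 to 3109075), which held another of the 20 strongest peaks at a second start site. The third lay between genes in the Antennapedia complex (3R, 6870281 to 6871891), 6693 bp downstream of the start of ftz, a pair-rule segmentation gene, and a further strong peak (3R, 6853735 to 6855265) lay upstream of the Hox gene Scr, at an offset of -4474 bp from its start. The fourth lay in the 5' UTR of Mef2, a transcription factor gene of muscle development (2R, 9942359 to 9943879). Others of the 20 strongest peaks were nearest to kmr, the homeobox gene NK7.1, CG10651, sick, CG6005, asRNA:CR45131, Cipc, Pvf3, Eip63E, CG3808, Dh31-R, Fas3, osp and Fas2. Fas2 and Fas3 encode cell adhesion molecules, Pvf3 a ligand of the PDGF and VEGF type, and Dh31-R a neuropeptide receptor. Of the 20 peaks, 11 lay within 500 bp of a start site, 4 between genes and 2 in introns, one of sick and one of gukh (3R, 19013520 to 19015763), whose nearest start site was that of CG6005. The 5 strongest peaks over 2 kb from any start site were those at InR, ftz, Scr and gukh and one 13817 bp from the start of CG10651 (2L, 20120354 to 20122280). Ranks repeated closely: 19 of the 20 were within the 40 strongest peaks of every replicate, and the exception, at Dh31-R, had rank 52 in replicate 3.

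Peaks gathered at promoters and were rare in coding exons and 3' UTRs. The summits of 3478 IDR peaks (32.7%) lay within 500 bp of an annotated transcription start site, 2.41 times the 13.6% of random placements, and the share in the 10650 strongest peaks of the replicates was 34.4% ± 1.33 (SD, n = 3). Coding exons held 0.901% of summits against 13.7% for random placements, 3' UTRs 0.854% against 4.45%, and intergenic sequence 20.4% against 27.2%. Introns held the most summits, 43.4% against 39.5%. Of the promoter summits, 2773 lay upstream of the start site and 704 downstream (79.8% upstream, 95% exact binomial interval 78.4 to 81.1), with a median offset from the start site of -118 bp. The strongest peaks were nearest to genes' starts: 62% of the first 100 peaks, 56.8% of ranks 101 to 500 and 27.5% of ranks 5001 to 10650 were promoter peaks.

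**Figure D1:**
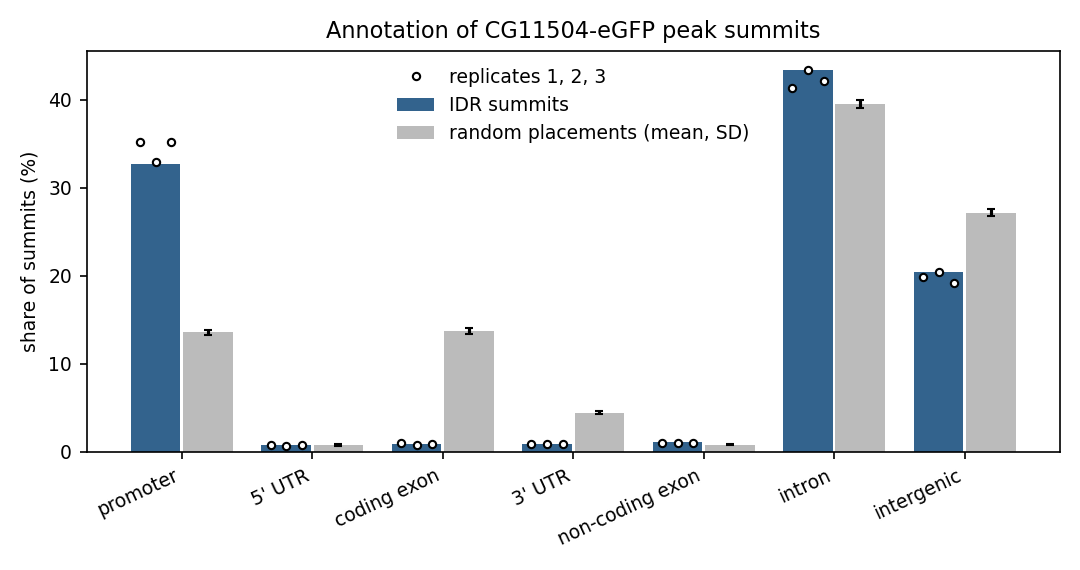
Share of peak summits (%) in each annotation class, in order of priority from promoter (within 500 bp of a start site) to intergenic, for the IDR list (dark bars), the 10650 strongest peaks of each of the 3 replicates (circles) and random placements on the same arm (grey bars, mean and SD of 1000 placements). Promoters held 32.7% of IDR summits against 13.6% of random placements, and coding exons 0.901% against 13.7%.

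The adjusted permutation p (Benjamini-Hochberg over 7 classes, two-sided) was 0.0028 for promoters, coding exons, 3' UTRs, introns and intergenic sequence, where 0.002 is the smallest unadjusted p that 1000 placements can give. Non-coding exons held 1.04% against 0.809% (adjusted permutation p = 0.021), a difference no longer past the threshold with a promoter window of 1000 bp on each side (0.582% against 0.468%, unadjusted permutation p = 0.11), among IDR peaks above the median signal (unadjusted p = 0.056), without replicate 2 (0.12) or without replicate 3 (0.08). With the 1000 bp window the intron share, 37.3% against 36.3%, was not past the threshold either after adjustment. The 5' UTRs held 0.714% against 0.78% (adjusted permutation p = 0.49), but with a promoter window of 250 bp they were past the threshold (1.08% against 1.33%, unadjusted permutation p = 0.024). In the whole pooled list, with its many weaker peaks, the promoter share was 21.7%, and in the 1000 strongest peaks of the replicates it was 53.6%.

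Of 13945 protein-coding genes, 3196 (22.9%; 24.5% ± 1.1, SD, n = 3 replicates) were bound, meaning that an IDR summit lay within 500 bp of one of their start sites. Among the preset gene groups, genes of cytoplasmic ribosomal proteins were bound at 54 of 93 (58.1%, 95% exact interval 47.4 to 68.2), among them RpL34b, RpS27, RpL31 and RpL32, while RpL10, RpL10Aa and RpL11 had no peak. Genes of Polycomb and Trithorax proteins, which keep developmental genes repressed or active, were bound at 15 of 23 (65.2%, 42.7 to 83.6), with ph-p, brm, E(z) and trr having the strongest peaks and Sce, esc and Su(z)12 none. Genes of Notch, Wnt, Hedgehog and EGFR signalling were bound at 15 of 25 (60%, 38.7 to 78.9), led by the Notch ligand Delta, the Hedgehog signal transducer smo, the EGFR ligand spi and its antagonist aos, whereas Ser, Su(H) and E(spl)m8-HLH had no peak. Mitochondrial ribosomal protein genes were bound at 30 of 73 (41.1%, 29.7 to 53.2), led by mRpL41, mRpS10, mRpS23 and mRpL23, and not at mRpL1, mRpL10 and mRpL12. Cell cycle and replication genes were bound at 14 of 31 (45.2%, 27.3 to 64.0), led by Cdk1, BubR1, Mcm2 and aurB, and not at CycB3, CycE and CycD.

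These 5 groups were bound more often than the other protein-coding genes (22.7% to 22.9%), in 3 of 3 replicates each. Fisher's exact test, two-sided and adjusted over 23 groups, gave p = 3.2e-12 for cytoplasmic ribosomal proteins, 8.2e-05 for Polycomb and Trithorax, 0.00028 for signalling, 0.0021 for mitochondrial ribosomal proteins and 0.024 for the cell cycle. The cell cycle group was not past the threshold without replicate 1 (35.5%, adjusted p = 0.0944, Fisher's exact test) or without replicate 3 (35.5%, adjusted p = 0.106), settings that count fewer IDR peaks. Peaks at ribosomal protein genes were of middling strength: among the 1000 strongest IDR peaks only 3 were at these genes' promoters, so that 3.23% of the group was bound there against 4.43% of other genes (adjusted p = 1, Fisher's exact test), and of the 5 groups only signalling remained past the threshold in those peaks.

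In 4 groups peaks were rare. Odorant, gustatory and ionotropic receptor genes, which serve the sense organs, were bound at 1 of 179 (0.559%, 0.0141 to 3.07), the exception being Ir67c, and Gr10a, Gr10b and Gr21a were among those without a peak. Genes of trypsin-like proteases and accessory gland proteins were bound at 1 of 75 (1.33%, 0.0338 to 7.21), at Sfp26Ad, and not at Jon25Bi, Jon25Bii or Jon25Biii. Cuticle protein genes were bound at 4 of 93 (4.30%, 1.18 to 10.6), namely Cpr92F, Cpr65Ea, Cpr67Fa1 and Cpr65Av, while Cpr100A, Cpr11A and Cpr11B had none. None of the 20 antimicrobial peptide genes was bound, AttA, AttB and AttC among them (a count of 0 allows up to 15%). The other protein-coding genes were bound at 23.0% to 23.2%, and each of the 4 groups was lower in 3 of 3 replicates. Adjusted p by Fisher's exact test was 7.1e-18 for the receptors, 8.6e-07 for the proteases, 7.8e-06 for the cuticle genes and 0.033 for the antimicrobial peptides. Members of a group that lie side by side are not independent counts, so the p-values and intervals can overstate the evidence. The call for the antimicrobial peptides was lost in 7 of the 9 alternatives. Among them was leaving out any of the 3 replicates in turn (adjusted p 0.0546 to 0.0616, Fisher's exact test), which counts fewer IDR peaks. In the 1000 strongest IDR peaks only the receptor group, of these 4, remained past the threshold.

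**Figure D2:**
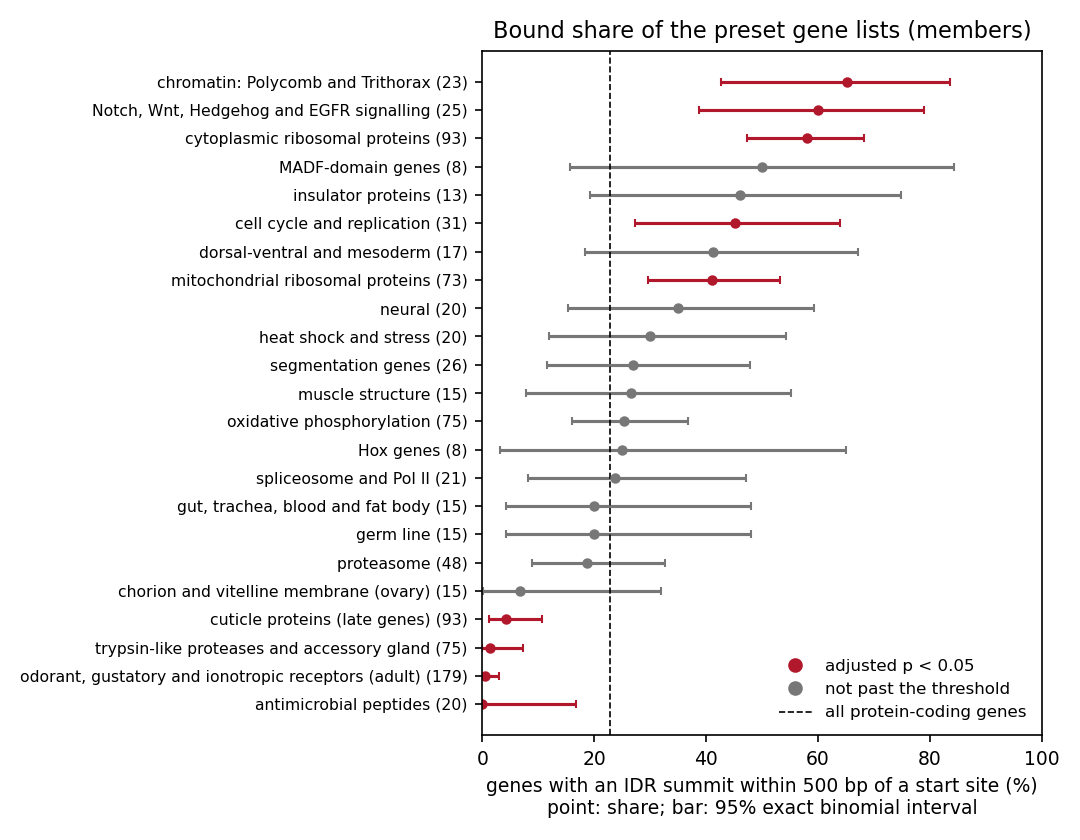
Share of genes (%) with an IDR summit within 500 bp of a start site in each of the 23 gene groups, with the number of members in brackets. Points are shares, bars are 95% exact binomial intervals, red marks an adjusted p under the threshold of 0.05 and the dashed line is the 22.9% of all protein-coding genes; Polycomb and Trithorax genes are highest at 65.2% and antimicrobial peptides lowest at 0%.

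The remaining 14 groups were not past the threshold. Bound were 4 of 8 MADF-domain genes (led by hng3), 6 of 13 insulator protein genes (Chro), 7 of 17 dorsal-ventral and mesoderm genes (sog), 7 of 20 neural genes (elav) and 6 of 20 heat shock and stress genes (Hsp27). Among segmentation genes 7 of 26 were bound (bcd), among muscle structure genes 4 of 15 (sls), among oxidative phosphorylation genes 19 of 75 (ND-39) and among Hox genes 2 of 8 (Antp). Bound were also 5 of 21 spliceosome and Pol II genes (U2af50), 3 of 15 genes of gut, trachea, blood and fat body (trh), 3 of 15 germ line genes (gcl), 9 of 48 proteasome genes (Rpn13) and 1 of 15 chorion and vitelline membrane genes (Vm32E). The lowest adjusted p of these, 0.17, was shared by the MADF-domain, insulator and mesoderm groups. In simulations, groups under 30 members with 2 times the usual share were found in only 2% to 31% of runs, so most differences of that size would be missed in the groups that small. With 1000 bp around start sites the dorsal-ventral and mesoderm group rose past the threshold (58.8% against 26.7%, adjusted p = 0.013, Fisher's exact test).

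Genes of small RNAs and of histones were counted apart. Of tRNA genes, 59 of 290 were bound (20.3%, 15.9 to 25.4; adjusted p = 0.40), close to protein-coding genes, whereas snoRNA genes were bound at 15 of 269 (5.58%, 3.15 to 9.03; adjusted p = 1.0e-13, Fisher's exact test). Of snRNA genes 5 of 32 were bound (15.6%, 5.28 to 32.8; adjusted p = 0.40, Fisher's exact test). None of 111 histone genes was bound (a count of 0 allows up to 2.70%, adjusted p = 9.8e-13, Fisher's exact test). These near-identical copies share reads and are not independent counts, so the result is uncertain.

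By chromosome arm, protein-coding genes on 2R were bound less often (574 of 2852, 20.1%, against 23.6% of genes on the other arms) and genes on 3L more often (679 of 2739, 24.8% against 22.5%). On the small chromosome 4, 5 of 80 genes were bound (6.25% against 23.0%). Adjusted p by Fisher's exact test over 6 arms was 0.00038 for 2R, 0.019 for 3L and 0.00041 for 4. The shares on X (24.3%, adjusted p = 0.14), 2L (23.7%, adjusted p = 0.37) and 3R (22.7%, adjusted p = 0.69) were not past the threshold of the exact test. The difference for 3L was lost among IDR peaks above the median signal (17.0%, adjusted p = 0.112, Fisher's exact test). X came past the threshold with 1000 bp around start sites (28.6%, adjusted p = 0.038, Fisher's exact test) and 2L, barely, with 250 bp (19.6%, adjusted p = 0.0498).

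Promoter peaks had more signal than the others. The median signal in the IDR list was 683 for promoter peaks and 511 for peaks farther than 500 bp from a start site (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give, where peaks are not independent replicates). In the 10650 strongest peaks of replicates 1, 2 and 3 it was 238 against 175, 282 against 217 and 187 against 155. The scale of the signal is not stated, so only the order of these medians is read.

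At the gene of the tagged protein itself, CG11504 (3R, 29997900 to 29999755, forward strand), no list had a peak in the gene or within 2 kb of it. The nearest IDR summit was 19087 bp away. Each replicate had a peak 14682, 14672 or 14683 bp away (summit at 29983218 in replicate 1, near the start of CG7896), with ranks 2157, 1991 and 1907 in replicates 1, 2 and 3. The nearest pooled summit was 15668 bp from the gene and had rank 13838.

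Peak centres were rich in A and T. Within 50 bp of IDR summits 33.3% of bases were G or C, against 41.6% at matched positions, which for promoter summits kept the offset from a start site, a difference of -8.28 percentage points (two-sided permutation p = 1e-05, the smallest possible). The 10650 strongest peaks of the replicates had 33.8% ± 0.727 (SD, n = 3). The dip was narrow in the IDR peaks other than the 500 strongest. Their GC content was 33.2% within 50 bp of the summit, 36.8% at 50 to 100 bp and 42.7% at 150 to 200 bp. There it passed the 42.1% found at 1500 to 2000 bp, and it was 43.8% at 200 to 400 bp. The 500 strongest IDR summits had 36.1% within 50 bp, against 40.9% at positions matched to them. In the full IDR list the dip was present at promoter summits (35.2% against 40.7% for promoter positions). It was also present in introns (32.2% against 39.8%) and between genes (31.6% against 41.1%). The strongest peaks were the exception: the first 100 IDR summits had 45.1% (45.1% ± 0.763 in the replicates, SD, n = 3), above the 40.6% of positions matched to them (permutation p = 0.001), an alternative chosen after the data were examined.

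**Figure D3:**
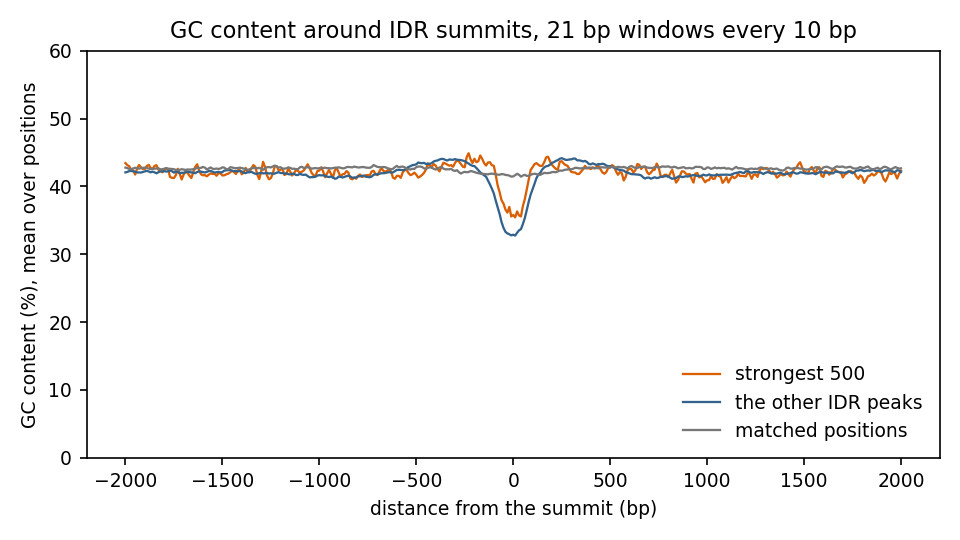
Mean GC content (%) in short windows by distance from the summit (bp), for the 500 strongest IDR peaks, the other IDR peaks and matched positions. The dip lies within about 100 bp of the summit, and GC content within 50 bp is 33.3% for IDR summits against 41.6% for matched positions.

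Of 2080 words of 6 bases, each joined with its reverse complement, 176 were more frequent within 50 bp of IDR summits than at matched positions and 769 were less frequent. Of the 176, 155 had at most 1 G or C, such as ATATTA, found at 22.2% of summits and 9.63% of matched positions, and AATATT (19.1% and 9%). Less frequent were GC-rich words such as GGATCC (0.329% and 1.39%) and CCAGGA (1.03% and 4.34%). In all 3 replicates and the IDR list alike, 139 words were more frequent and 594 less frequent. The threshold was an adjusted p of 0.01 by Fisher's exact test with an odds ratio over 1.5 or under 0.67.

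Among 18 preset motifs, the TATA box word TATAAA was found at 24.1% of summits and 13% of matched positions (adjusted p = 3.3e-96 by Fisher's exact test), and the homeodomain word TAATTA at 10.8% and 6.42% (9.9e-30). GTATTT, known as Ohler 6, was at 15.4% and 9.65% (4.4e-36), the GATA factor word WGATAR at 22.4% and 16.9% (1.7e-23), the GCN repeat at 1.61% and 0.826% (4.7e-07), and GGTCACAC, the word of the promoter factor M1BP, at 0.892% and 0.366% (2.4e-06). Lower at summits were the GAGA factor word (9.03% and 11.3%, 1.0e-07), the E-box CANNTG (34.1% and 39.0%, 1.7e-13), its forms CACGTG (0.676% and 1.16%, 0.00038) and CAGCTG (3.32% and 4.94%, 9.1e-09), CCGCCG (1.68% and 3.62%, 2.4e-18), the initiator (8.83% and 10%, 0.0034) and the BEAF-type word CGATA (11.9% and 13.3%, 0.0029). For each of these 13 motifs, the shares in 3 of 3 replicates lay on the same side of the IDR list's matched share. No test was run per replicate. The positions were not matched on base composition (33.3% GC at summits, 41.6% at matched positions). A rise of AT-rich motifs or a fall of GC-rich ones therefore cannot be told apart from the AT-rich centre of the peaks. The word ATATTA, for one, rose more (odds ratio 2.68) than TATAAA (2.12) or TAATTA (1.77). The DRE core (0.930% and 0.704%, adjusted p = 0.090, Fisher's exact test), Ohler 7 (0.58), the Zelda word CAGGTA (0.053), the CTCF core (0.058) and the CA repeat (0.11) were not past the threshold. Against the peaks' own flanks, 300 to 400 bp from the summit, the BEAF-type word was instead the more frequent one at summits (11.9% and 10.6%, adjusted p = 0.00097, Fisher's exact test), and the GCN repeat was not past the threshold (adjusted p = 0.63). Other calls were lost for the GAGA factor word within 100 bp of the summit (adjusted p = 0.214, Fisher's exact test), for M1BP (0.679) and CACGTG (0.202) among IDR peaks above the median signal, and for CGATA (0.282) and CAGCTG (0.0763) against positions of the same annotation class. Calls were also gained. The CA repeat was lower at summits in every alternative but the 100 bp window, as against own flanks (1.36% and 4.26%, adjusted p = 1.9e-48, Fisher's exact test), positions of the same class (4.2e-05) and without 1 replicate (0.0105 to 0.0159). The CTCF core was lower with 100 bp (adjusted p = 0.00066, Fisher's exact test), against own flanks (1.5e-06), above the median signal (0.026) and without replicate 1 (0.0076). Zelda was lower with 100 bp (0.0027) and against the same class (0.00027). The DRE core was higher with 100 bp (0.00012) and against own flanks (1.1e-13), as was Ohler 7 (0.015 and 9.7e-05).

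The strongest peaks carried a different word, in an alternative chosen after the data were examined. Among the 500 strongest IDR peaks, ATGTTG was at 34.4% of summits against 6.04% of positions matched to those peaks (odds ratio 8.16, adjusted p = 5.4e-65, Fisher's exact test), and GCAACA at 36.2% against 7.28%. The share with ATGTTG was 69.3% ± 4.73 (SD, n = 3 replicates) in the 100 strongest peaks of each replicate, 25% ± 3.91 in ranks 101 to 500, 14.5% ± 0.462 in ranks 501 to 1000 and 8.91% ± 0.449 in ranks 5001 to 10650. Joined, the words make the palindrome GCAACATGTTGC. It was present at 16% of the first 100 IDR summits (9.43 to 24.7, 95% exact interval) and at 0.159% of ranks 5001 to 10650. Of its 207 occurrences on the 6 arms, 136 (65.7%, 58.8 to 72.1) lay within 100 bp of an IDR summit, and the share was 66.3% ± 2.01 (SD, n = 3) for the 10650 strongest peaks of the replicates, while at most 1.60% of the genome lay as close to a summit. The 136 sites were in introns (51), promoters (42), intergenic sequence (32), coding exons (5), non-coding exons (3), 5' UTRs (2) and a 3' UTR (1).

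**Figure D4:**
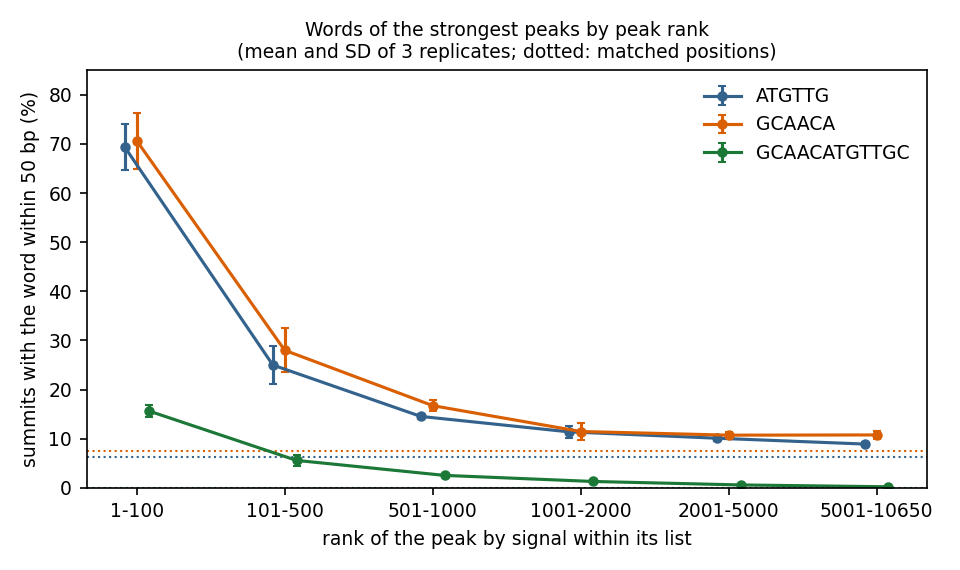
Share of summits (%) with the words ATGTTG, GCAACA and GCAACATGTTGC within 50 bp, by rank of the peak by signal within its list. Points and bars are the mean and SD of the 3 replicates and dotted lines are the shares at matched positions; ATGTTG falls from 69.3% in the first 100 peaks to 8.91% in ranks 5001 to 10650.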

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

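Both results here were chosen after the data were examined, and neither enters the comparisons above. Of the 19350 pooled peaks below the IDR threshold, 26.9% matched a peak in each of the 3 full replicate lists, against 1.99% on average and 2.35% at most for random placements. The pooled list was made from these same replicates, so a share above random placements is no separate test of the weaker peaks. The weaker peaks lie outside the IDR list, and no explanation was tested.

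The pooled list lacked some peaks that every replicate had. Of 7703 peaks of replicate 1 that were matched among the 10650 strongest peaks of both other replicates, 56 (0.727%) overlapped no pooled peak. They included peaks near the start sites of Atg9, an autophagy gene (2R, 16294029 to 16294477), CG8067, CG17982 and ArfGAP3, which were chosen after their values were seen, and the peak near CG7896 that lay closest to CG11504. No explanation was tested for these either.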

How the results depend on the processing

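Promoter, replicate and signal results kept their direction and side of the threshold in each alternative run. The GC difference did so too except in the 100 strongest IDR peaks, where it was reversed to 4.56 percentage points. Chosen after the data were examined were the strongest 1000, 500 or 100 IDR peaks, matching on annotation class or own start sites, and leaving out replicates for classes, arms, motifs and GC content. Of 509 alternatives over all results, 417 had the direction and side of the threshold of the reported value, or its size within the spread or, for counts, within 1.5 times. Single items fell below a threshold in 27 cases (15 gene groups, 2 of which also changed direction, 6 motifs, 5 annotation classes and 1 arm) and rose past one in 20, 16 of them motifs. Counts of items past a threshold often moved a little, and 4 shrank and 3 grew by more than 1.5 times. With 1 group of samples, no other split of the samples could be tested. The IDR list itself was not remade without a replicate. Of 40 named bound genes 27 stayed bound with 250 bp, 37 or 38 without 1 replicate and 24 in the 1000 strongest IDR peaks. The unknown depth leaves open how far weak peaks could be missed. Except where fewer peaks or genes were counted, the cause was not tested.

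The promoter share of replicate peaks was 53.6% for the 1000 strongest and 23.0% for all listed. Rank agreement was 0.912 with any overlap and 0.882 to 0.898 without 1 replicate. In the 1000 strongest IDR peaks 2 groups, not 9, were past the threshold, and 348 words were less frequent; in the 500 strongest 44 words were more and 17 less frequent. Against own flanks 294 words were more frequent, and of 8-base words 1322 were more and 1350 less frequent.

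Other changes of direction were seen in groups, motifs and arms not past the threshold, apart from those named with their group. With 250 bp the bound shares were 18.75% for proteasome, 15% for neural, 13.3% for muscle and 20% for germ line genes, and 18.2% for arm 3R. With 1000 bp they were 25% for Hox, 26.7% for muscle and 23.8% for spliceosome genes. Among IDR peaks above the median signal they were 16.7% for proteasome, 14.7% for oxidative phosphorylation, 12.5% for Hox, 7.69% for segmentation and 20% for germ line genes, 16.7% for 3R and 14.7% for X, and Ohler 7 was at 3.21%. In the 1000 strongest they were 3.23% for cytoplasmic ribosomal proteins (past the threshold in the full list), 0% for the cell cycle (likewise), 4% for oxidative phosphorylation, 0% for segmentation and muscle, and 6.67% for gut, trachea, blood and fat body. Lists matched on own start sites were bound at 35.6% (Hox) and 42.6% (muscle). Without 1 replicate, shares were 12.5% to 25% for Hox, 20% to 26.7% for muscle, 20% for germ line and 19.0% to 23.8% for spliceosome genes, and 19.0% to 20.2% for 3R. The CA repeat was at 3.52% within 100 bp, the BEAF-type word, past the threshold as reported, at 11.9% against own flanks, and the CTCF core at 3.13% against the same annotation class.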

Other observations

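Apart from the gene group shares and the gene lists matched on neighbouring start sites, the tests in this part were chosen after the data were examined. Promoter peaks of cytoplasmic ribosomal protein genes differed in sequence from those of the other bound protein-coding genes. The DRE core TATCGATA, the site of the promoter factor Dref, was within 50 bp of 20.4% of 54 ribosomal protein summits and 2.34% of 2481 others (adjusted p = 9.2e-07, Fisher's exact test over 18 motifs), and the BEAF-type word CGATA of 50% and 17.6% (adjusted p = 9.2e-07). CGATA is part of TATCGATA, so these results overlap. The 11 ribosomal protein summits with the DRE core were among the 27 with CGATA. The GC content of the ribosomal protein summits was 40.5% against 34.6%. The TATA box was at 11.1% and 23.1% (adjusted p = 0.15 by Fisher's exact test), not past the threshold.

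IDR summits were rare in annotated transposable elements, which held 0.225% of them and 5.93% of the bases of the arms. Reads of such copies can be lost in mapping, so this is given as a value only. GC content also varied with rank: it was 45.1% at the first 100 IDR summits, above the 40.6% of positions matched to them, 33.9% in ranks 101 to 500 and 30.4% in ranks 501 to 1000.

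The palindrome GCAACATGTTGC and its word ATGTTG at the strongest peaks were weighed first. The word was the more common: ATGTTG was at 72% of the first 100 IDR summits and the whole palindrome at 16%. In ranks 101 to 500 the shares were 25% and 5.25%. A chance choice among the many words predicts no excess in data left out of the choice, but with the word chosen on the other arms, ATGTTG was at 28.8% of the 80 X peaks among the 500 strongest (19.2 to 40, 95% exact interval) against 5.47% of matched X positions. Base composition is argued against by the other palindromes of the same half-site bases, of whose 562 sites 2.49% lay near a summit (1.37 to 4.14), and copies of an annotated transposable element by the 0% of all 207 palindromes, near a summit or not, that lay in one (a count of 0 allows up to 1.45%). Sites with 1 mismatch lay near a summit in 13.4% of 868 cases (11.2 to 15.8) against 65.7% for the exact palindrome. By place of the mismatch in the half-site, the share ran from 3.98% (position 5) to 22.1% (position 4). The test on X covered the word ATGTTG only, not the whole palindrome. The palindrome was chosen from these same summits, so part of its lead over the other sequences can follow from that choice. The hypothesis that CG11504, or a protein bound with it, may recognise this palindrome or a part of it stays open. Which protein does was not tested, since no library with another tagged protein was analysed here.

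The AT-rich centre of the peaks was weighed next. The annotation classes of the summits do not account for it, since the GC difference was -7.13 percentage points against positions of the same class. A GC bias of the sequenced fragments stays open. GC content by distance was read in the IDR peaks other than the 500 strongest. Their GC content at 50 to 100 bp from the summit was -5.36 percentage points from that at 1500 to 2000 bp. Short fragments of 200 bp centred on the summit would give this. Long fragments would lower GC content at 200 to 400 bp too. There it was higher by 1.65 percentage points in the same peaks (SE 0.0759 over peaks). A preference of the bound protein for AT-rich sequence, or open chromatin that is itself AT-rich, may equally underlie the dip, and neither was tested.

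The peaks at ribosomal protein promoters, 58.1% of the group, were weighed last. Gene density is argued against by random gene lists matched on neighbouring start sites, bound at 22.6%, and a signal common to all housekeeping promoters by the oxidative phosphorylation genes, bound at 25.3% (16.0 to 36.7, against 47.4 to 68.2). Mitochondrial ribosomal protein genes (41.1%) and cell cycle genes (45.2%) were raised too, so a signal at part of the housekeeping promoters stays open. The palindrome's word does not account for them, as ATGTTG was at 7.41% of these summits and 10.1% of the other bound promoters. With the DRE core at some of these peaks, the tagged protein may be recruited there with another promoter factor, or these promoters may collect chromatin without it. A library without the tag, not analysed here, would tell these apart. Ribosomal protein promoters without a peak were not examined, so the DRE core may be a trait of these promoters whether bound or not.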
